A study of Mus musculus with 2 samples.

How the data were processed

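Whole-lung RNA of mice was sequenced for 2 genotypes. The control mice carried floxed Foxf1 alleles alone, and the knockout mice carried the same alleles together with Pdgfb-iCreER, a tamoxifen-inducible Cre recombinase expressed in endothelial cells. Per the labels, the background strain was C57/BL6, and lung RNA of several mice was pooled for each genotype, so that each group holds 1 library. The number, sex and age of the pooled mice, the tamoxifen schedule, and the part of Foxf1 that the floxed alleles delete are not given in the sources used here. Each library was assigned to its group by the genotype in its label.

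The authors deposited FPKM values, which are fragments scaled to transcript length and to the mapped fragments of the library, for 28107 RefSeq transcripts per library, with a position, a length and a status for each. Per the file headers, the second measurement is coverage, the depth of aligned bases per transcript base, which is a constant multiple of FPKM within a library. The genome build mm9 and the tool DESeq are named in the submitters' processing notes. The role of DESeq, the aligner, the quantification tool and its version are not given in the sources used here. The status was OK for 27778 transcripts of the knockout library and 27777 of the control library, LOWDATA for 294 in each, and FAIL for 35 and 36. No record was mitochondrial. Starts are printed counted from 1, since 3284 records had a length equal to their end minus their start and 0 had that length plus 1. FPKM divides by the total of a library, so a few abundant transcripts can shift all other values. Reads of near-identical genes can also be divided differently between the 2 libraries.

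FPKM values of all transcripts of a symbol were summed, which gave 22072 genes, of which 3793 had more than 1 record and 4621 were listed at 0 in both libraries. The log2 ratio is log2(FPKM + 1) of the knockout library minus that of the control library, a scale that understates the difference of genes with low values. Folds printed for single genes are plain FPKM ratios. Gene counts used the 12929 genes with a mean FPKM of 1 or more and a fold of 2 on the log2(FPKM + 1) scale. Members of gene lists were counted at a fold of 1.5 on the same scale.

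Depth was estimated from the coverage. Coverage times length, over genes with 1 transcript and very few reads, peaked at 47.7 bases in the knockout library and 47.6 in the control library, taken as the bases that 1 read adds. On this scale the knockout library holds 10.4 M reads on transcripts and the control library 13.2 M, a ratio of 1.27. A transcript of 2000 bases with 10 reads has an FPKM of 0.393 in the knockout library and 0.304 in the control library. For each gene the 95% interval of the FPKM ratio was computed from these approximate reads as an exact conditional (Clopper-Pearson) interval. It covers counting error only. It leaves out differences between mice, between pools and between library preparations, which 1 library per genotype cannot show. No p-values were computed across genes, and every difference compares these libraries without a replicate check.

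A total of 46 gene lists was fixed before the data were examined, together with the grouping, the floors, the fold thresholds and most of the alternative settings. They cover endothelial subtypes (pan-endothelial, general capillary, aerocyte capillary, arterial, venous, lymphatic), endothelial signalling (sphingosine-1-phosphate, junctions, VEGF and angiopoietin, BMP and TGF-beta, Notch), inflammation, interferon and coagulation, other cell types and tissues of the lung and its surroundings, and processes (cell cycle, extracellular matrix, immediate early genes, heat shock, clock). The remaining lists hold sex-linked genes, forkhead genes, chromosomal neighbours of Foxf1 and of Pdgfb, surfactant and lipid genes, ribosomal protein genes and housekeeping genes. A list was described by the median log2 ratio of its members over the floor and by the percentile of that median among 10000 random lists of the same size, matched on mean expression in 20 bins. The percentile describes these libraries and is no test of the genotypes. With 43 lists evaluated, 2.15 would fall outside the central 95% of random lists if each held unrelated genes. Members of a list can vary together and some lists share members, so more can fall outside without an effect of genotype. Intervals of a median come from 2000 bootstrap draws of its members.

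The text names genes by a rule fixed at the same time. It names Foxf1 and S1pr1, all S1P receptors, and the 12 highest and 12 lowest log2 ratios among genes with a mean FPKM of 2 or more. From each list it takes the highest, the lowest and the 2 most abundant members over the floor. Symbols without a protein-coding style, such as small nucleolar RNAs and microRNAs, were counted but not named. They took 6 places above and 8 places below before the 12 named genes were reached. Of the genes this rule takes, 1 is not reported here. Genes named outside this rule are marked as chosen after their values were seen.

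The computation was tested on simulated reads drawn at the depths of this knockout and control pair for 12918 genes, of which 12519 were unchanged. Counting noise alone put 14 unchanged genes at least 2-fold apart. Of the genes changed 4-fold, 100% passed 2-fold; of those changed 2-fold, 17.6% passed 2-fold and 94.1% passed 1.5-fold; of those changed 1.5-fold, 26.5% passed 1.5-fold. The counting interval held the true ratio for 95.4% of the genes. All 10 simulated lists of 20 genes shifted by 0.4 on the log2 scale fell outside the central 95% of random lists in the right direction. Of 100 unchanged lists, 5 fell outside it. All simulated lists held randomly drawn genes with independent counting noise, unlike lists whose members vary together. The alternatives tried were 4 other scalings between the libraries, pseudocounts of 0.1 and 3, no floor and a floor of 5, folds of 3 and 1.5, the most abundant transcript of a gene only, members on 1 list only, unmatched random lists and means in place of medians. Leaving out genes with a LOWDATA or FAIL record, leaving out genes under 300 bases, and asking for a counting interval clear of 1 were chosen after seeing the data. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.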

Results

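Lung transcriptomes were compared between a pool of mice in which endothelial Foxf1 was targeted and a pool of control mice, with 1 library each. Foxf1 encodes a forkhead transcription factor expressed in lung mesenchyme and endothelium. The series title links it to endothelial barrier function and to the gene of the sphingosine-1-phosphate (S1P) receptor S1PR1. The comparison asks which lung transcripts differ between the pools. The control mice carried no Cre, so effects of Cre or its transgene cannot be told apart from those of reduced Foxf1. The knockout library held about 10.4 M reads on transcripts and the control library 13.2 M. None of the differences has a replicate check, and the intervals given after folds are 95% counting intervals.

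Foxf1 was 4.59-fold lower in the knockout pool (3.97 to 5.35). Its FPKM was 72.1 in the control pool and 15.7 in the knockout pool, from about 1260 and 212 reads. The files list it as Foxf1a, with 1 transcript of 1062 bases on chromosome 8 from 123608374 to 123610779 (mm9). Whether this record covers the deleted part is not known, since that part is not given in the sources used here. S1pr1, on chromosome 3 from 115413351 to 115417973 (mm9), was almost level between the pools. Its FPKM was 124 in the control pool and 118 in the knockout pool, 1.05-fold lower (1.01 to 1.09). Of the other S1P receptors, S1pr3 was 1.34-fold higher in the knockout pool (1.26 to 1.44) and S1pr4 was 1.32-fold lower (1.13 to 1.55). S1pr2 (18.5 and 20.3 FPKM) and S1pr5 (1.21 and 1.21 FPKM) differed by less than their counting error. The S1P pathway list of 20 members over the floor had a median log2 ratio of 0.16, at percentile 84.9 of random lists. Its lowest member was Sphk1, a kinase that makes S1P, at 1.94-fold lower (1.67 to 2.25), and its highest was Tiam1, a Rac exchange factor, at 2.12-fold higher (1.80 to 2.51). Gnai2 (208 and 288 FPKM) and Rac1 (199 and 209 FPKM) were its most abundant members.

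Among 12929 genes with a mean FPKM of 1 or more, 485 were at least 2-fold higher in the knockout pool and 162 at least 2-fold lower, so that 75.0% of these genes were higher. The median log2 ratio of all these genes was 0.05, and log2 values of the libraries correlated across genes with a Pearson r of 0.950, genes not being independent replicates. The highest named genes were mostly mitotic: Ccna2, Pbk, Ube2c, Prc1, Cdc20, Birc5, Top2a, Ckap2, Fam64a and Cdca3. Ccna2, which encodes cyclin A2, was 14-fold higher (11.5 to 17.4), and the DNA topoisomerase gene Top2a was 12.2-fold higher (10.5 to 14.2). The remaining pair of the highest genes was the imprinted RNA H19, at 0.295 FPKM in the control pool and 16.5 in the knockout pool, and the acute-phase gene Saa3, at 1.43 and 21.2 FPKM. The lowest genes included Hpgd, which encodes a prostaglandin-degrading enzyme and was 7.04-fold lower (6.62 to 7.49), and Npr3, the natriuretic peptide clearance receptor gene, at 8.22-fold lower (7.48 to 9.03). Lyve1, a hyaluronan receptor gene, was 5.90-fold lower (5.53 to 6.28), and Tmem100, a gene of the endothelial BMP pathway, was 4.75-fold lower (4.49 to 5.04). Cyp1a1 was 13.0-fold lower (9.72 to 17.6), Fibin 5.28-fold lower (4.57 to 6.10), Igfbp3 4.84-fold lower (4.29 to 5.47), Grtp1 7.91-fold lower (4.9 to 13.0) and Pcdhac2 11.7-fold lower (8.27 to 16.9). Whether reads shared with related genes affect the value of Pcdhac2 was not checked. Rps27, Hba-a2 and Hbb-b2 also ranked among the lowest, but they share sequence with near-identical genes. Rps27 together with Gm9846, a copy chosen after its values were seen, had 665 FPKM in the control pool and 521 in the knockout pool. Hba-a2 together with Hba-a1 had 417 and 376 FPKM, and Hbb-b2 together with its 2 related genes had 3266 and 2894 FPKM. With a pseudocount of 0.1, 676 genes were higher and 267 lower, with a pseudocount of 3, 275 and 104, and with a floor of 5, 268 and 113.

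**Figure D1:**
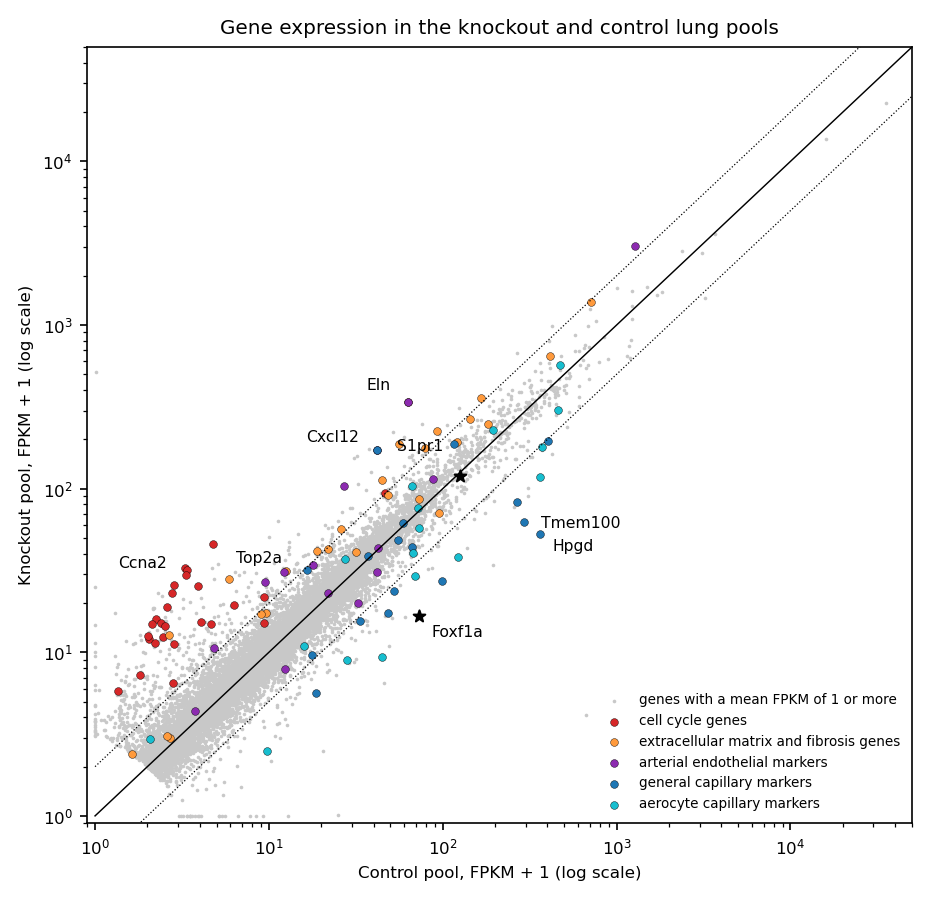
FPKM + 1 of each gene in the control pool (horizontal log axis) and the knockout pool (vertical log axis), with 5 gene lists coloured (a gene on 2 lists takes the colour lower in the legend), stars for Foxf1a and S1pr1, a solid line at equality and dotted lines at 2-fold. Cell cycle genes lie above the upper dotted line with 1 exception, and Foxf1a lies below the lower one at 72.1 and 15.7 FPKM.

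Most markers of lung capillaries were lower in the knockout pool and most arterial markers were higher, while markers shared by all endothelium were centred near equality. General capillary markers had a median log2 ratio of -1.05 (-1.68 to 0.04 over draws of its members), below all 10000 random lists, with 11 of 17 members at least 1.5-fold lower and 3 higher. Besides Hpgd and Tmem100, the fatty acid transporter gene Cd36 was 2.07-fold lower (2.02 to 2.12). Cxcl12, also on the arterial list, went the other way at 4.2-fold higher (4.03 to 4.37), as did Aplnr (15.5 and 30.9 FPKM) and Gpihbp1 (114 and 186 FPKM), both chosen after their values were seen. Aerocyte markers, which mark the capillary cells specialised for gas exchange, had a median of -0.61 (-1.61 to 0.23), below all random lists, with 9 of 17 members at least 1.5-fold lower and 1 higher. Fibin was the lowest of them. Kdr, a VEGF receptor gene, was the highest on the log2(FPKM + 1) scale, at 1.56-fold higher (1.51 to 1.62). Emp2, also on the alveolar type 1 list, was 1.53-fold lower (1.5 to 1.56), and Igfbp7 was 1.20-fold higher (1.17 to 1.24). Arterial markers had a median of 0.93, above all random lists, with 8 of 15 members at least 1.5-fold higher and 2 lower. Eln, which encodes elastin, was 5.42-fold higher (5.23 to 5.62) and Mgp, a calcification inhibitor gene, was 2.39-fold higher (2.34 to 2.44), while the Notch ligand gene Dll4 was 1.66-fold lower (1.52 to 1.80). The 5 members within 1.5-fold included Efnb2 (41.5 and 42.1 FPKM) and Edn1 (21.0 and 22.1 FPKM), both chosen after their values were seen. Eln and Mgp are also expressed by smooth muscle cells and fibroblasts, and Eln is on the extracellular matrix list as well. Whole-lung RNA does not show in which cells the arterial list was higher.

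**Figure D2:**
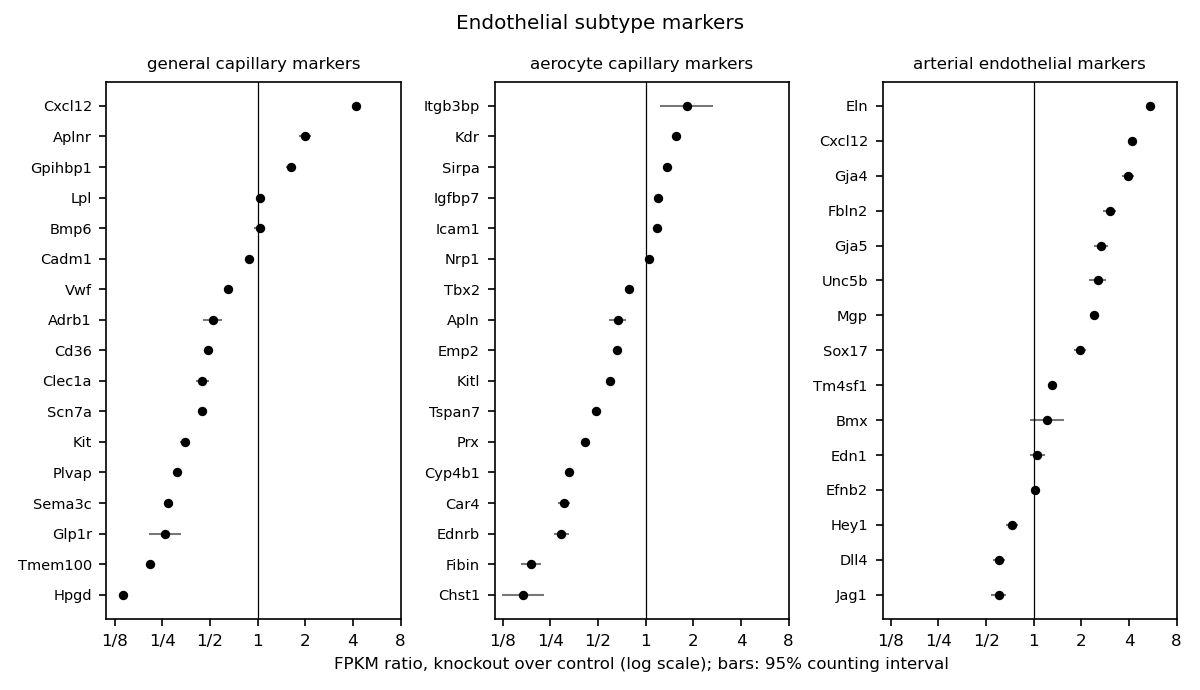
FPKM ratio of the knockout over the control pool for each general capillary, aerocyte and arterial marker over the floor (horizontal log axis, points), with bars for 95% counting intervals. Of the general capillary, aerocyte and arterial markers, 12, 11 and 3 lie below equality.

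The pan-endothelial list of 30 genes had a median of 0.06, at percentile 25, which turned to -0.01 and -0.02 under 2 of the other scalings, with 6 members at least 1.5-fold higher and 6 lower. Emcn, which encodes endomucin, was 5.11-fold higher (4.71 to 5.55), and Ramp2 and Calcrl, which encode the adrenomedullin receptor, were 2.62-fold lower (2.49 to 2.76) and 3.06-fold lower (2.97 to 3.14). Egfl7 was 1.31-fold higher (1.26 to 1.36). Venous markers had a median of 0.25 (percentile 95.9) and a mean of -0.26, with 4 of 12 members at least 1.5-fold lower and none higher. Among them were Lyve1 and Vwf, at 1.53-fold lower (1.48 to 1.59), while Bst1 was 1.48-fold higher (1.30 to 1.68). Lymphatic markers had a median of 0.35 (percentile 98.3) and a mean of -0.06, since Lyve1 lay far below Flt4, at 1.51-fold higher (1.39 to 1.64), and Pdpn, at 1.28-fold higher (1.20 to 1.36).

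Endothelial junction genes were centred near equality, with a median of 0.04 (percentile 22.9) that was negative under 3 of the other scalings. Of 30 members, 4 were at least 1.5-fold higher and 1 was lower. The connexin gene Gja4 was the highest, at 3.94-fold (3.62 to 4.31), and the tight junction gene Cldn5 the lowest, at 1.75-fold lower (1.67 to 1.83). Pecam1, at 241 and 237 FPKM, differed by less than its counting error, and Ctnnb1 was 1.23-fold higher (1.20 to 1.26). VEGF and angiopoietin genes had a median of 0.13 (percentile 75.0), from Pgf at 2.68-fold higher (2.0 to 3.67) to the receptor gene Tek at 1.45-fold lower (1.39 to 1.52), with Vegfa 1.19-fold lower (1.16 to 1.22). BMP and TGF-beta genes had a median of 0.07 (percentile 48.1), which was -0.01 under 1 other scaling, and a mean of -0.09, with 3 of 24 members at least 1.5-fold higher and 6 lower. The BMP target Id1 was 2.06-fold higher (1.92 to 2.22) and the coreceptor gene Eng 1.35-fold higher (1.31 to 1.39), whereas the receptor genes Bmpr2 (20.6 and 6.57 FPKM) and Acvrl1 (175 and 70.3 FPKM), chosen after their values were seen, were lower along with Tmem100. Notch genes had a median of -0.06 (percentile 9.40) and a mean of 0.06, with Jag2 at 2.55-fold higher (2.35 to 2.77), Dll4 lower, Hey1 at 1.37-fold lower (1.26 to 1.49) and Hes1 at 42.5 and 39.4 FPKM. Coagulation and activation genes had a median of 0.37 (percentile 99.9), with 6 of 18 members at least 1.5-fold higher and 2 lower. Thbs1, which encodes thrombospondin 1, was 2.65-fold higher (2.53 to 2.78), Icam1 1.18-fold higher (1.14 to 1.21), and Thbd, the thrombomodulin gene, 2.08-fold lower (2.03 to 2.14).

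Cell cycle genes were higher in the knockout pool without exception among the 26 on the list, all at least 1.5-fold, with a median log2 ratio of 2.54 (2.0 to 2.82), above all random lists. Ccna2 was the highest and the helicase gene Mcm4 the lowest, at 1.69-fold higher (1.51 to 1.91). The 2 most abundant were Pcna, at 2.04-fold higher (1.88 to 2.21), and Ube2c, at 12-fold higher (9.06 to 15.9). The median was 3.15 with a pseudocount of 0.1 and 1.82 with a pseudocount of 3. Extracellular matrix genes had a median of 0.95, above all random lists, with 19 of 26 members at least 1.5-fold higher and none lower. Eln was the highest, Sparc was 1.95-fold higher (1.92 to 1.98) and Bgn 1.55-fold higher (1.52 to 1.58), and Spp1 was the lowest, at 1.35-fold lower (1.26 to 1.45).

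Inflammatory cytokines and chemokines had a median of 0.76, above all random lists, with 11 of 20 members at least 1.5-fold higher. Saa3 was the highest, Lcn2, which encodes lipocalin 2, was 3.33-fold higher (3.10 to 3.58), the chemokine gene Ccl6 was 1.84-fold higher (1.74 to 1.96), and Ccl5 was the lowest at 1.68-fold lower (1.30 to 2.19). Interferon-stimulated genes had a median of 0.45, above all random lists, with 11 of 25 members at least 1.5-fold higher and none lower. They ranged from Rsad2, at 3.85-fold higher (3.09 to 4.86), to Gbp2, at 1.20-fold lower (1.09 to 1.32), with Ifit3 at 1.71-fold higher (1.56 to 1.88) and Bst2 at 1.33-fold higher (1.21 to 1.45). Neutrophil markers had a median of 0.48 (percentile 99.9), with S100a8 1.41-fold higher (1.14 to 1.76) and Fpr1 at 10.4 and 8.66 FPKM. Markers of monocytes and interstitial macrophages had a median of 0.48 (percentile 99.98), led by C1qb at 2.27-fold higher (2.0 to 2.58), with Apoe 1.22-fold (1.18 to 1.27) and Ly6c2 1.36-fold higher (1.21 to 1.53). Treml4 was near the floor at 1.77 and 1.56 FPKM. Alveolar macrophage markers had a median of 0.46 (-0.24 to 1.12), above all random lists, with 7 of 16 members at least 1.5-fold higher and 3 lower. On this list Ctsk was 6.04-fold higher (5.27 to 6.96), Fabp5 2.04-fold higher (1.86 to 2.23), Chi3l3 1.06-fold higher (1.03 to 1.10) and Ear2 1.78-fold lower (1.51 to 2.09). B and plasma cell markers had a median of 0.32 (percentile 99.1), from Fcer2a at 2.12-fold higher (1.49 to 3.04) to Igj at 11.9 and 10.6 FPKM. The abundant Cd79b was 1.45-fold higher (1.2 to 1.75) and Cd79a stood at 12.1 and 13.0 FPKM. T and NK cell markers had a median of -0.15 (percentile 4.84), inside the central 95% of random lists, with 2 of 16 members at least 1.5-fold lower. On this list Gzmb was 2.03-fold lower (1.21 to 3.53) and Gzma 1.57-fold lower (1.22 to 2.05), with Ccr7 at 4.34 and 4.19 FPKM and Lck at 2.90 and 3.51 FPKM.

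Airway epithelial markers were lower in the knockout pool. Ciliated cell markers had a median of -0.46, below all random lists, with 22 of 23 members below equality and 8 at least 1.5-fold lower. Tppp3 was 2.01-fold lower (1.88 to 2.15) and Sec14l3 1.59-fold lower (1.56 to 1.63), while Tuba1a, a tubulin gene of many cell types, was 1.5-fold higher (1.45 to 1.55). Club cell markers had a median of -0.41, below all random lists. The secretoglobin gene Scgb1a1 was 1.55-fold lower (1.54 to 1.56) and took 1.31% of aligned bases in the knockout pool against 2.06% in the control pool. Cbr2 was 2.21-fold lower (2.17 to 2.25), and Scgb3a1, at 1.58 and 3.40 FPKM, alone lay above equality among the 12 club cell members over the floor, by less than its counting error. Alveolar type 1 markers had a median of -0.22 (percentile 0.14), with Cyp2b10 2.36-fold lower (2.25 to 2.49), Hopx 1.48-fold lower (1.44 to 1.53), Ager 1.12-fold lower (1.10 to 1.14) and Igfbp2 1.73-fold higher (1.66 to 1.81). Alveolar type 2 markers were centred near equality, with a median of 0.07 (percentile 27.2) that was -0.01 under 1 other scaling and -0.02 over members of no other list. Sftpc was 1.15-fold lower (1.15 to 1.16), Lyz2 1.03-fold lower (1.02 to 1.04) and Sftpa1 1.49-fold lower (1.47 to 1.51), while the desaturase gene Scd1 was 2.53-fold higher (2.49 to 2.58). Surfactant and lipid genes had a median of 0.12 (percentile 70.2), from Cd36 to Fabp4, a fatty acid binding protein gene at 3.27-fold higher (2.15 to 4.96).

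Mesenchymal lists lay modestly above equality. Fibroblast markers had a median of 0.30 (percentile 99.6), from Cthrc1 at 4.33-fold higher (3.11 to 6.19) to Inmt at 1.90-fold lower (1.85 to 1.95), with Mfap4 2.32-fold higher (2.26 to 2.37). Smooth muscle markers had a median of 0.36 (percentile 99.3), with Tagln 2.34-fold (2.21 to 2.47) and Acta2 2.23-fold higher (2.11 to 2.36) and Itga8 1.22-fold lower (1.17 to 1.28). Pericyte markers had a median of 0.38 (percentile 99.7), with Cspg4 2.35-fold (2.08 to 2.65), Cox4i2 1.83-fold (1.63 to 2.06) and Postn 1.61-fold higher (1.56 to 1.67) and Kcnj8 1.58-fold lower (1.15 to 2.18). Mesothelial markers had a median of 0.41 (percentile 99.6), with Lrrn4 2.0-fold (1.70 to 2.36) and Krt19 1.69-fold higher (1.59 to 1.80), Efemp1 at 74 and 76.5 FPKM, and Rspo1 at 6.24 and 5.45 FPKM.

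Platelet markers had a median of -0.59, below all random lists, with 6 of 11 members at least 1.5-fold lower. Ppbp was 2.74-fold lower (2.24 to 3.37) and Pf4 was 1.40-fold higher (1.08 to 1.79). Erythroid markers had a median of -0.08 (percentile 12.6), with Hba-a1 at 393 and 376 FPKM, Hbb-b1 at 158 and 149 FPKM and Tfrc 1.39-fold higher (1.29 to 1.51). Lists for other tissues had few expressed members. Of the 18 cardiac genes, 5 were over the floor, with a median of 0.68 (percentile 99.1), from Myl7 at 1.60 and 4.75 FPKM to Tnni3 at 2.24 and 1.32 FPKM, with Actc1 at 15.9 and 26.1 FPKM. Of the 14 adipose genes, 4 were over the floor, with a median of -0.41 (percentile 0.820), from Cidec at 2.13-fold lower (1.59 to 2.90) to Thrsp at 2.09 and 3.36 FPKM, with Lipe at 20.1 and 18.6 FPKM. No median was taken for skeletal muscle (Pgam2 alone, 1.06 and 1.53 FPKM), for thymus and lymph node (Ccl25 at 1.30 and 1.05 FPKM and Cd1d1 at 3.7 and 4.41 FPKM) or for airway cartilage, gland and basal cells (Ltf alone, 1.16 and 1.75 FPKM).

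Clock genes were lower in the knockout pool as a list, with a median of -0.83, below all random lists, and 9 of 17 members at least 1.5-fold lower against 2 higher. The transcription factor genes Dbp and Tef were 3.30-fold lower (2.92 to 3.73) and 2.70-fold lower (2.56 to 2.85), and Nr1d1 was 1.80-fold lower (1.71 to 1.89). Arntl, which encodes the activator BMAL1, was 2.37-fold higher (1.93 to 2.91). Heat shock and stress genes had a median of -0.13 (percentile 0.825), with Hspa1b 2.43-fold lower (2.15 to 2.75), Hsp90aa1 1.32-fold lower (1.28 to 1.37), Hspa8 1.44-fold lower (1.41 to 1.47) and the metallothionein gene Mt2 3.35-fold higher (2.92 to 3.85). Immediate early genes had a median of 0.32 (percentile 99.5), from Nr4a1 at 3.16-fold higher (2.79 to 3.59) to Jun at 1.54-fold lower (1.46 to 1.62), with Klf2 1.44-fold higher (1.36 to 1.52) and Ier3 at 85.4 and 83.0 FPKM.

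Forkhead genes had a median of -0.41, below all random lists, with 13 of 16 members below equality. Foxf1 was the lowest, Foxp1 was 1.49-fold lower (1.40 to 1.59), and Foxm1, a forkhead factor of dividing cells, was 7.72-fold higher (6.29 to 9.61). Chromosomal neighbours of Foxf1 had a median of 0.17 (percentile 74.4), which was -0.13 without a floor. Of the 10 neighbours on the list, 2 were below the floor. Fendrr, also on the aerocyte list, was not found under its symbol, so its level is not known here. None of the 7 over the floor differed by 1.5-fold, among them Cox4i1 (172 and 205 FPKM), Map1lc3b (136 and 113 FPKM) and Fbxo31 (10.1 and 7.49 FPKM). The neighbourhood of Pdgfb, whose regulatory sequence drives the Cre, had a median of 0.03 (percentile 38.8), negative under 3 of the other scalings. Pdgfb itself was 2.75-fold higher (2.60 to 2.91). Only the knockout mice carried Pdgfb-iCreER, and whether reads of this transgene were counted as Pdgfb was not tested. Mgat3 was 1.68-fold lower (1.43 to 1.98), and Rpl3 and Atf4 were 1.21-fold (1.16 to 1.25) and 1.14-fold higher (1.08 to 1.21). Sex-linked genes had a median of -0.08 (percentile 23.9), with the Y-linked Ddx3y at 21.1 and 18.8 FPKM and Eif2s3y at 21.6 and 26.7 FPKM, present in both pools. Ribosomal protein genes had a median of -0.06 (percentile 2.78), all 27 within 1.5-fold on the log2(FPKM + 1) scale, including Rplp1 (848 and 848 FPKM), Rpl10 (686 and 568 FPKM) and Rpl30 (6.53 and 10.3 FPKM). Housekeeping genes had a median of 0.28 (percentile 96.8), with Gapdh 1.77-fold (1.70 to 1.85) and Actb 1.69-fold higher (1.66 to 1.71), and Eef1a1 1.12-fold lower (1.11 to 1.14).

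**Figure D3:**
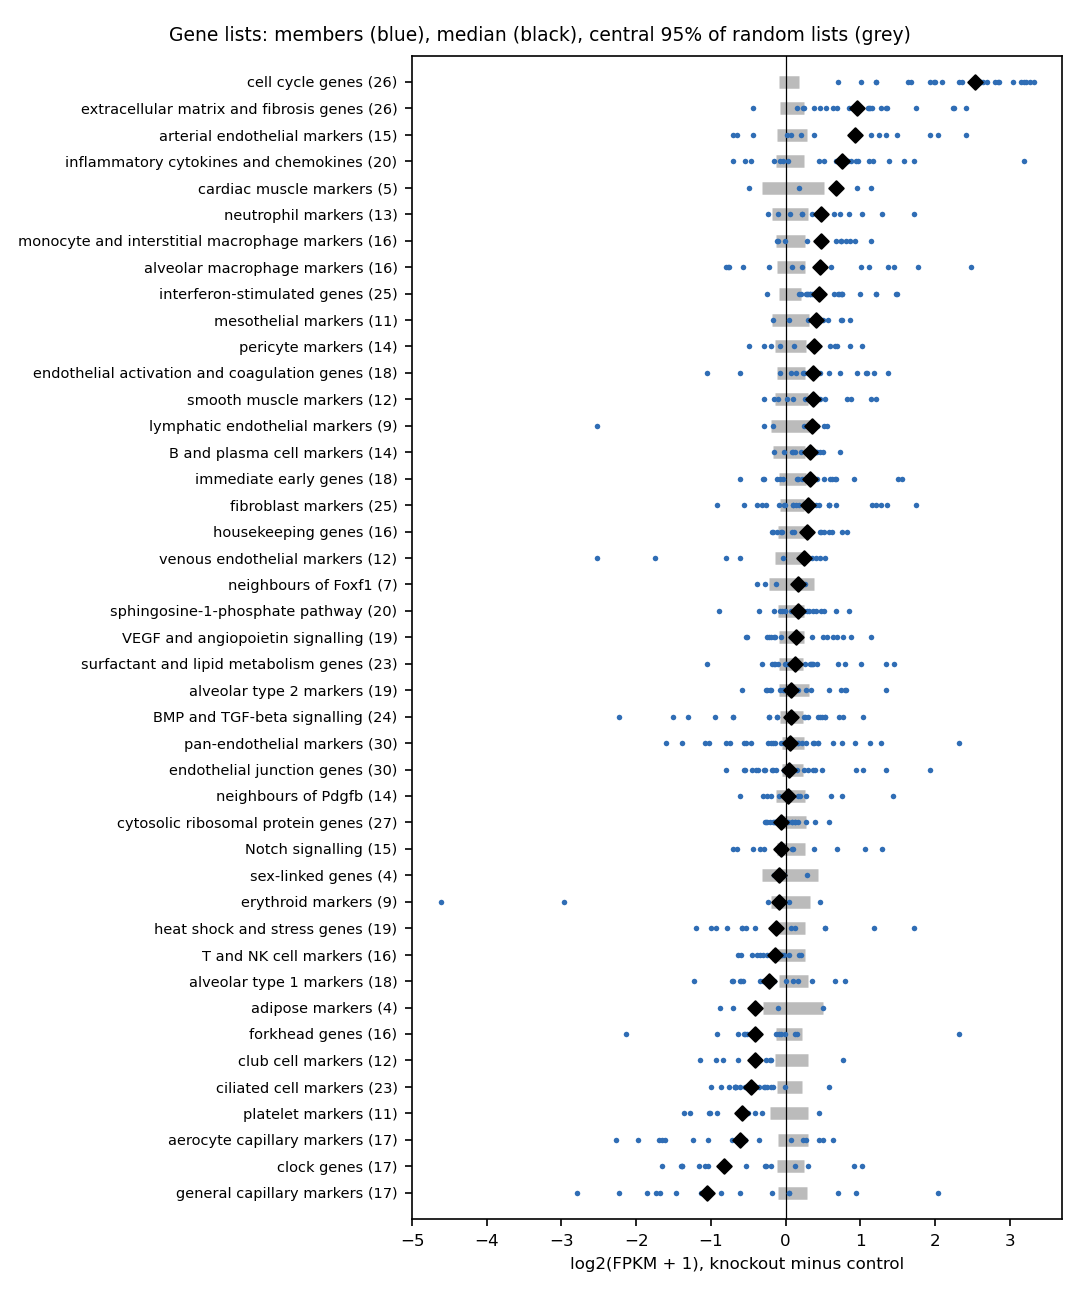
Median log2(FPKM + 1) difference, knockout minus control, of the 43 evaluated gene lists (diamonds, members over the floor in parentheses), with single members as blue points and the central 95% of random lists as grey bars. The cell cycle list has the highest median at 2.54 and the general capillary list the lowest at -1.05.

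Of the 43 evaluated lists, 17 lay above and 10 below the central 95% of random lists. Among these 27, 18 stayed outside under every alternative setting, and the other 9 (lymphatic, B and plasma cell, fibroblast, smooth muscle, pericyte, cardiac, adipose, immediate early and heat shock) came inside under at least 1. The interval over members included 0 for the general capillary, aerocyte, lymphatic, inflammatory, alveolar macrophage, alveolar type 1, fibroblast, smooth muscle, cardiac, adipose, immediate early and heat shock lists.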

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

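Leaving out genes with a LOWDATA or FAIL record, leaving out short RNA genes and asking for a counting interval clear of 1 were chosen after seeing the data; the other settings were planned. Foxf1 stayed between -2.21 and -2.01 on the log2 scale over 9 alternatives and S1pr1 between -0.15 and -0.07. S1pr1 was -0.13 with a trimmed mean of log2 ratios and -0.15 with equal totals without the 50 most abundant genes. The scalings move all genes by -0.05, -0.06, -0.01 and -0.08. The other 167 named genes gave 1503 values, of which 191 moved beyond the counting interval. Among genes at least 1.5-fold apart with a counting interval clear of 1, 0 reversed. Sign changes of genes nearer equality were not counted, and the scalings are too small to reverse a 1.5-fold difference. General capillary markers stayed between -1.31 and -0.76, aerocyte markers between -1.04 and -0.61, arterial markers between 0.76 and 1.04 and clock genes between -0.90 and -0.57. Of 16 lists inside the central 95% of random lists, 10 stayed inside under every setting, while the venous, VEGF, T and NK cell, erythroid, ribosomal and housekeeping lists went outside under at least 1. The scalings move members and random lists nearly alike, so they hardly test this. No paired analysis was possible because each genotype has 1 library. Genes with few reads limit all counts: 14162 genes of the knockout library and 14326 of the control library had 10 or more reads.

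Genes at least 2-fold lower numbered 267 with a pseudocount of 0.1; with a pseudocount of 3, 275 genes were higher and 104 lower. With a floor of 5, 268 were higher. At 3-fold, 204 were higher and 62 lower, and at 1.5-fold, 1217 and 599. These settings change the counts by construction. The share of higher genes was 75.0%, and between 69.2% and 74.3% under the other scalings.

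Ribosomal protein genes were at -0.11 with the median ratio set to 0, -0.12 with the trimmed mean and -0.14 without the 50 most abundant genes, moved by the shift of all genes, as was S1pr1. With no floor they stayed at -0.056, at percentile 1.84. For the other lists below the cause was not tested, except that single low members pulled down 2 of the means. These were Lyve1 (-2.52) for the lymphatic mean and Hba-a2 (-4.61) for the erythroid mean. Hba-a2 shares sequence with Hba-a1, and the 2 summed were at -0.15. With a pseudocount of 0.1, the lymphatic list was at 0.36, the B and plasma cell list at 0.43 and the cell cycle list at 3.15; with a pseudocount of 3, the lymphatic list was at 0.25, platelet markers at -0.40 and the cell cycle list at 1.82. With no floor, venous markers were at 0.30, smooth muscle at 0.18, cardiac at 0.11, adipose at -0.11 and immediate early genes at 0.19. With a floor of 5, lymphatic markers were at 0.30, B and plasma cell at 0.15, fibroblast at 0.24 and housekeeping genes at 0.28. With the most abundant transcript only, lymphatic markers were at 0.35, B and plasma cell at 0.26 and smooth muscle at 0.22. Over members on 1 list only, lymphatic markers were at 0.31, VEGF genes at 0.35, fibroblast at 0.16 and immediate early genes at 0.22. Against unmatched random lists, T and NK cell markers (-0.15) and housekeeping genes (0.28) moved outside the central 95%. As means, the lymphatic list turned to -0.059, venous markers were at -0.26, T and NK cell at -0.19, B and plasma cell at 0.28, smooth muscle at 0.41, pericyte at 0.31, cardiac at 0.49, adipose at -0.30, erythroid at -0.85 and heat shock genes at -0.13. Without LOWDATA or FAIL genes the cardiac list was at 0.43.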

Other observations

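Some transcripts outside the lists fixed at the start also differed between the pools. These genes and the 6 lists below were chosen after the data were seen. A list of liver-type transcripts, drawn up after the data were seen, had a median log2 ratio of 1.49 over 11 genes, 9 of them at least 1.5-fold higher, which describes these genes and tests nothing. Alb, which encodes albumin, had 8.98 FPKM in the control pool and 49.6 in the knockout pool, 5.52-fold higher (4.86 to 6.28), while the more abundant Hp had 402 and 455 FPKM. Mest, an imprinted gene like H19, was 7.04-fold higher (5.95 to 8.40). Ramp3, a partner of Calcrl, was 8.62-fold higher (6.73 to 11.1), the reverse of Ramp2 and Calcrl, and Lrg1 was 5.10-fold higher (4.69 to 5.55). Tip cell and sprouting genes had a median of 0.30 (-0.51 to 1.05), with 7 of 17 at least 1.5-fold higher and 3 lower. Among them Adm, the ligand gene of the adrenomedullin receptor, had 3.27 and 14.4 FPKM, and Esm1 was lower at 11.6 and 7.83 FPKM.

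The tests in the next paragraphs on the share of endothelial cells, on lymphoid tissue and on time of day, and those that 1 library per genotype leaves open, were chosen only after the result was seen. The test on younger mice was set before its value was known, but on a list drawn up after the data were seen. Most capillary markers were lower in the knockout pool, with most arterial markers higher. Fewer endothelial cells of all vessels would lower the shared endothelial markers about as far. The 29 pan-endothelial genes outside the capillary lists had a median of -0.023 (-0.23 to 0.27). They are the pan-endothelial list without Kdr, whose median was already known, and ran from -1.60 (Calcrl) to 2.32 (Emcn). An equal loss from all vessels as the whole cause would put this median well below 0, where it did not lie. Since the median was known beforehand, this describes the genes and is no independent test. Opposing changes among the members could also hide a smaller loss. The median cannot decide on a loss of capillary cells alone. A few abundant transcripts setting the FPKM scale are argued against by the small size of the scaling. Totals set equal without the 50 most abundant genes shifted the knockout values by only -0.08 on the log2 scale. The general capillary median was then -1.13, which follows from this shift by construction. A difference between the pooled mice other than genotype stays open with 1 library per genotype, and the genotype itself was not tested apart from it.

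The higher cell cycle genes were weighed in the same way. Lymphoid tissue dissected with the knockout lungs would bring lymphocyte transcripts, but 32 T, NK, B cell and thymus markers had a median of 0.016 (-0.11 to 0.19). They did not move as 1 group, since B and plasma cell markers were at 0.32 (0.10 to 0.41) and T and NK cell markers at -0.15, both far below the cell cycle median of 2.54. Younger mice in the knockout pool may also show more cycling cells. Imprinted and perinatal growth genes, a list without the higher H19 and Mest, had a median of 0.25 (0.08 to 0.65) over 14 genes. Of these, 12 lay above equality, with 4 at least 1.5-fold higher and 0 lower. The median leaves this explanation open. A difference between the pooled mice other than genotype or age cannot be told apart from the genotype with 1 library each.

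Evening-phase clock genes had a median of -1.08, with 11 of 11 below equality. Morning-phase genes had a median of 0.52 (-0.19 to 1.03), with 3 of 4 above equality and Cry1 below, at 4.57 and 3.88 FPKM. The difference of the medians was -1.61 (-2.36 to -0.85), the pattern that another time of day at collection could give. The 5 cycling genes outside the clock list had a median of 0.14 (-0.62 to 0.22), with no common direction. Loss of rhythm in the knockout lungs at the same time of day cannot be told apart from this with 1 library per genotype.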
